A study of Mus musculus with 14 samples.

How the data were processed

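Exosomes were collected from cultures of CD11b+F4/80+ macrophages of adipose tissue of C57BL/6 mice, and their RNA was taken up with a kit for biofluids, per the labels' protocols. The labels put 7 libraries in the obese group and 7 in the lean group. The submitters' processing notes name FastQC, MultiQC, Trimmomatic 0.30, Novoalign, edgeR and limma, without their roles. The genome build and the miRNA annotation are not given in the sources used here. The age labels step by 1 week per sample in order of listing and were not used. The listing puts the obese libraries before the lean ones, so ages that run on through it would differ between the groups. In that case age cannot be told apart from the difference between obese and lean.

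The material analysed is 1 table of the authors' comparison, with the columns that limma's ranking of results has: a log2 fold change, a mean expression, t, p, adjusted p and B. Fold changes and mean expression are on the log2 scale in the authors' deposited table, and the scaling between libraries behind them is not given in the sources used here. The deposited t is a score, a moderated t with no fixed range. The deposited p-values are unadjusted and adjusted, and B is the natural log of the odds of a difference, per the file headers. How the authors normalized, filtered and weighted libraries before the test, and how they assigned reads that match several hairpins, is likewise not given in the sources used here. Whether strand was used is not given there either, so mir-126a and mir-451a, annotated opposite another hairpin, are uncertain. The same holds for mir-142a and mir-486a, which were not placed here but are known to lie opposite mir-142b and mir-486b. These steps decide how reads shared between copies or with other RNAs enter a row.

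The design fixed before the data were examined assumed a value per library. Since the table holds 0 columns of per-library values, no model was fitted to libraries here: the authors' fold changes and p-values were taken as deposited, and hairpins with an adjusted p under 0.05 are called. The depth of each library is unknown, so no counting interval was given, and the number of miRNAs detected, the share of the 10 most abundant and the total count per library were not analysed here. The deposited adjusted p equals a Benjamini-Hochberg adjustment of the deposited p over 539 rows, with a largest difference of 1.46e-14. From t and p in the authors' deposited table, 17.9 total degrees of freedom were recovered, the same for every row. A fit of 14 libraries in 2 groups leaves 12, and the difference of 5.91 is what limma's shared variance adds if the fit had no other term. The standard error of a hairpin is its deposited log2 fold change divided by t, and 95% intervals use the recovered degrees of freedom. The median standard error was 1.02 among the 180 least abundant hairpins, 1.10 among the 179 in the middle and 0.76 among the 180 most abundant. At those errors and the smallest absolute t that was called, 3.53, log2 fold changes of 3.61, 3.88 and 2.69 are needed for a call. No hairpin of the least abundant 180 was called.

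The naming rule, fixed before the data were examined, takes mir-155, then the 10 largest called fold changes in each direction among the more abundant rows, split at the median mean expression of 2.34. It further takes the 5 most abundant hairpins, over both groups since group means are not given, and 2 to 4 members of smallest p of each list. Hairpins named beyond the rule were chosen after their values were seen: let-7d, mir-17, mir-20a, mir-132, mir-150, mir-181c, mir-181d, mir-221, mir-365-1, mir-378a and mir-425 for contrast with their lists or neighbours, and mir-3470b, 1 of 7 called hairpins outside the rule.

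The 20 lists were written as mature miRNAs before the data were examined and matched by hairpin stem, so a list member is a hairpin and each copy counts. Lists of at least 3 hairpins were tested with cameraPR of limma 3.58.1 (R 4.3.3) on z-scores of the deposited t, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over 19 lists. The planned camera test on values per library, its version with an estimated correlation, and fry need those values and could not be run, so no call here is known to hold with an estimated correlation. On simulated t values for 539 rows, drawn independently, 4.5% of lists without a change had a p under 0.05 in 200 simulations. Real copies and neighbours tend to have similar values, so this share need not hold for lists that contain them. Lists shifted by 2 in t were recovered in 97% of simulations at the median and in 53.5% for the least favourable list. In the same simulations with 200 rows changed by 4 on the log2 scale, 83.3% of these were called and 3.07% of calls were false. So many changed rows loosen the Benjamini-Hochberg cutoff, whereas 30 hairpins were called in the authors' deposited table. Both shares therefore hold for that setting alone and do not give the sensitivity of the real comparison.

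Hairpins were placed by gene symbol on GENCODE M21, which annotates the mouse assembly GRCm38, and 515 of 539 (95.5%) matched. The build the authors used may differ, so the coordinates are those of GENCODE M21 alone. A hairpin shares sequence where any 20 bases of it occur in sense in a transcript of a gene at another place that is not a miRNA. The host gene of another copy of the same miRNA counts as such a gene. Ribosomal 45S precursor RNA is not in that annotation and was not searched. Fisher's exact tests, permutations and bootstraps used SciPy 1.17.1, NumPy 2.4.6 and pandas 2.3.3 in Python 3.11.15, and plots matplotlib 3.10.9.

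Alternatives tried on the table were a minimum of 2-fold, an adjusted p under 0.1, a minimum mean log2 expression of 3.32 (log2 of 10), 1 hairpin per stem, recentring on the median of all hairpins or of the 180 most abundant, and leaving out hairpins that share sequence. For the lists a preset correlation of 0.05, ranks, leaving out mir-155 or the miR-181 hairpins, and 10000 random lists matched on expression were added.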

Results

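Small RNA was sequenced from exosomes that adipose tissue macrophages (ATMs) release. ATMs are the CD11b+F4/80+ macrophages of fat tissue, and exosomes are small vesicles that carry microRNAs (miRNAs) between cells. The cells came from C57BL/6 mice and were kept for 72 h in medium with 10% serum cleared of exosomes, after which vesicles were collected by ultracentrifugation. The labels describe 7 libraries of exosomes from obese ATMs and 7 from lean ATMs. The values analysed here are those of the authors' deposited table, which compares the groups for 539 miRNA hairpins with a log2 fold change, a mean log2 expression and a p-value each. It holds no value for any single library, so the total count per library, the spread within a group and the group means are unknown here. Nothing in the labels says whether each library came from a separate animal, so the p-values measure only the spread between these libraries. If the age labels hold and run on through both groups, age cannot be told apart from the difference between obese and lean. The rows name hairpins, and the 5p and 3p arms of a hairpin cannot be told apart.

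The table does not say which group is the numerator of its fold changes, so directions are given as positive or negative. Published work on this material, known from outside these data, reported more miR-155 in exosomes of obese ATMs. The hairpin mir-155 is positive in the authors' deposited table, so under that report a positive value stands for a higher level in the obese group. With the sign taken from mir-155, its own direction is no evidence, and the directions of all other hairpins hold only relative to it.

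The comparison asks which miRNAs differ in level between exosomes of obese and lean ATMs. In the authors' deposited table, 30 of 539 hairpins had an adjusted p under 0.05. On the positive side, with mir-155, were 11 hairpins, among them the miR-181a and miR-181b copies, mir-210, mir-222, mir-140 and let-7i. The 19 on the negative side included mir-511, mir-690, mir-365-2, mir-29b-1 and the 3 copies of mir-692. The 30 hairpins make up 26 stems when copies of one miRNA are counted once, 9 positive and 17 negative. Called log2 fold changes in the authors' deposited table ran from 1.82 to 5.37 on the positive side and from −2.50 to −7.03 on the negative side. The positive hairpins were the more abundant, with a median mean log2 expression of 11.02 against 4.93 for the negative ones in the authors' deposited table. At an unadjusted p under 0.05, 95 hairpins passed in the authors' deposited table, 46 positive and 49 negative, where chance would give 26.95. The split depended on scaling and on low rows. Recentring all fold changes by 0.34, the median of the 180 most abundant hairpins, gave 8 positive and 25 negative calls, and leaving out hairpins with a mean log2 expression under 3.32 gave 16 of each.

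**Figure D1:**
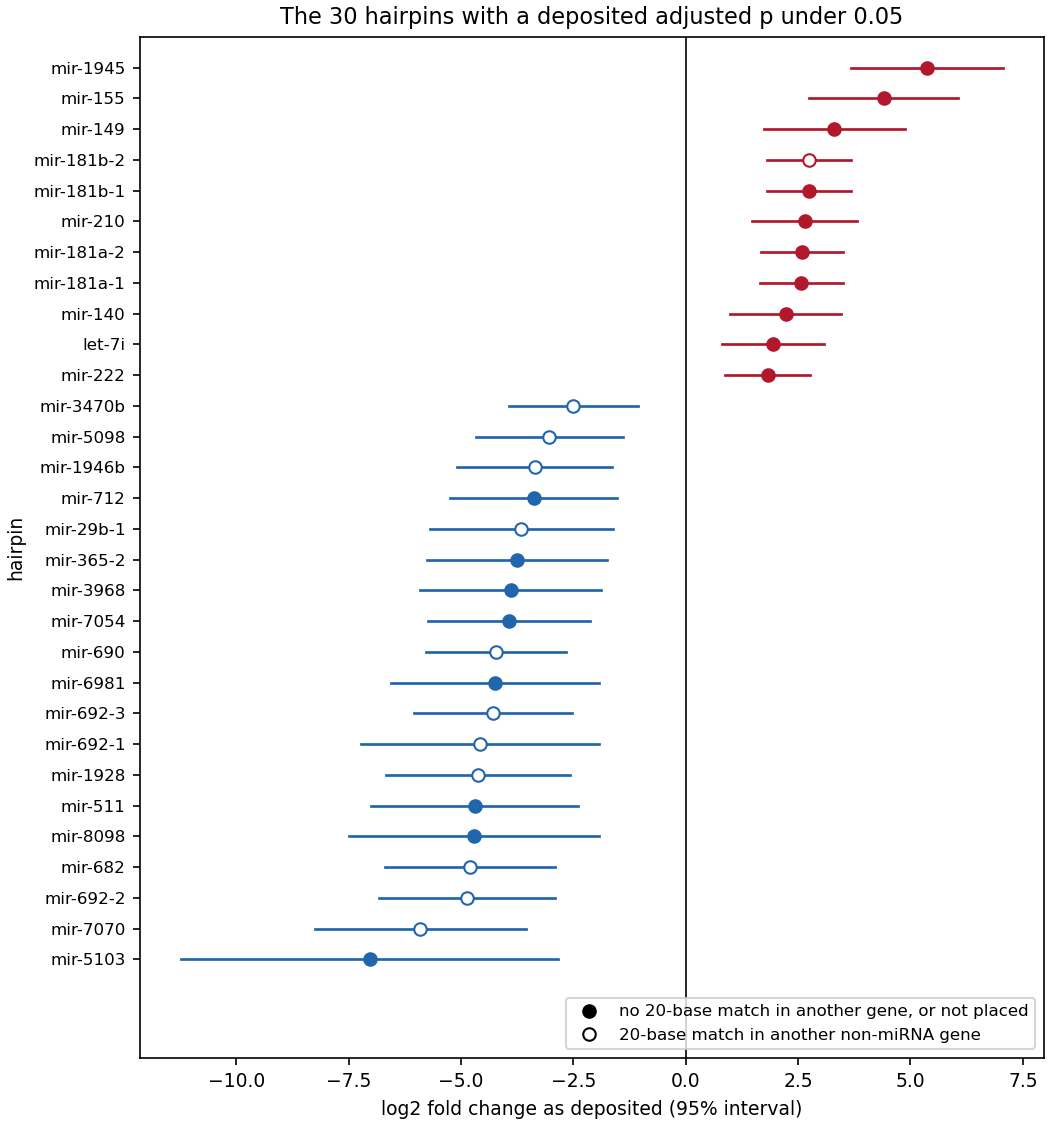
The 30 hairpins with a deposited adjusted p under 0.05, ordered by log2 fold change as deposited (horizontal axis), with lines for the 95% interval derived from the deposited fold change and t. Filled points have no 20-base match to another non-miRNA gene or could not be placed, and open points have such a match: 1 positive hairpin (mir-181b-2) and 11 negative ones.

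The hairpin mir-155, a miRNA induced in macrophages by inflammatory stimuli, had a log2 fold change of 4.41 (21.2-fold) in the authors' deposited table, with an adjusted p of 0.00205. The standard error that follows from the fold change and t in the authors' deposited table is 0.79, which gives a 95% interval from 2.75 to 6.06. Its mean log2 expression in the authors' deposited table was 11.02. On the mouse assembly GRCm38, GENCODE M21 places mir-155 (ENSMUSG00000065397.1) on chromosome 16, bases 84714140 to 84714204 of the plus strand, within an exon of the long noncoding RNA Mir155hg.

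Beside mir-155, the positive side held the miR-181 group, which takes part in lymphocyte development. The copies mir-181a-1 and mir-181a-2 had log2 fold changes of 2.57 and 2.58, each with an adjusted p of 0.00174, in the authors' deposited table. The copies mir-181b-1 and mir-181b-2 had 2.74 and 2.75, each with an adjusted p of 0.00142, in the authors' deposited table. Copies of one miRNA can share mature reads, and the values within each of these pairs are nearly equal, so each pair is taken as in effect 1 measurement. The hairpins mir-181a-1 and mir-181b-1 lie together on chromosome 1, from base 137966455 to base 137966718, in an exon of the noncoding RNA A430106G13Rik, and mir-181a-2 and mir-181b-2 lie on chromosome 2, from base 38852735 to base 38853918, outside annotated hosts. The hypoxia-responsive mir-210 was at 2.64 (adjusted p = 0.00704) in the authors' deposited table. In the same authors' deposited table, mir-149, in an intron of the glypican gene Gpc1, was at 3.31 (adjusted p = 0.0112). The hairpin mir-140, within Wwp2, was at 2.22 (adjusted p = 0.0310), and let-7i at 1.95 (adjusted p = 0.0383), in the authors' deposited table. The largest positive value of the authors' deposited table was that of mir-1945, at 5.37 (adjusted p = 0.00142), a little-studied hairpin of mean log2 expression 3.60. After recentring by 0.34, mir-140 and let-7i no longer passed (adjusted p = 0.0742 and 0.0977).

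The negative side held mir-511, which lies in an intron of Mrc1, the gene of the mannose receptor CD206 that marks alternatively activated macrophages. Its log2 fold change was −4.70 (95% interval −7.00 to −2.40) with an adjusted p of 0.0148, and its mean log2 expression 4.17, from the authors' deposited table. GENCODE M21 places mir-511 (ENSMUSG00000077897.1) on chromosome 2, bases 14261003 to 14261081. The hairpin mir-690, in an intron of Fgf12, was at −4.23 (adjusted p = 0.00192) in the authors' deposited table, and shares a stretch of 20 bases with transcripts of 44 other genes. The 3 copies of mir-692 were at −4.30, −4.59 and −4.87 in the authors' deposited table, and all share 20 bases with Ftl1, which encodes ferritin light chain. Likewise mir-682, at −4.80 (adjusted p = 0.00299) in the authors' deposited table, shares 20 bases with Rpl37a, a ribosomal protein gene. The most negative value in the authors' deposited table was −7.03, for mir-5103 (adjusted p = 0.0432, mean log2 expression 12.09), followed by −5.90 for mir-7070 in an intron of Fbxw9 (adjusted p = 0.00299), which shares 20 bases with 1 pseudogene. The hairpins mir-8098, in an exon of Wdfy2, and mir-3968 were at −4.70 (adjusted p = 0.0425) and −3.89 (adjusted p = 0.0218) in the authors' deposited table. Of the 18 negative hairpins that could be placed on the annotation, 11 (61.1%) share 20 bases with a gene that is not a miRNA, against 1 of 11 positive ones. For a hairpin with copies, such as mir-29b-1, that gene may be the host of another copy. Where reads of hairpins that share sequence come from cannot be told from the table. Without the hairpins that share sequence, 9 positive and 6 negative calls were left, and mir-5103, mir-8098 and let-7i no longer passed (adjusted p = 0.0602, 0.0602 and 0.0561).

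**Figure D2:**
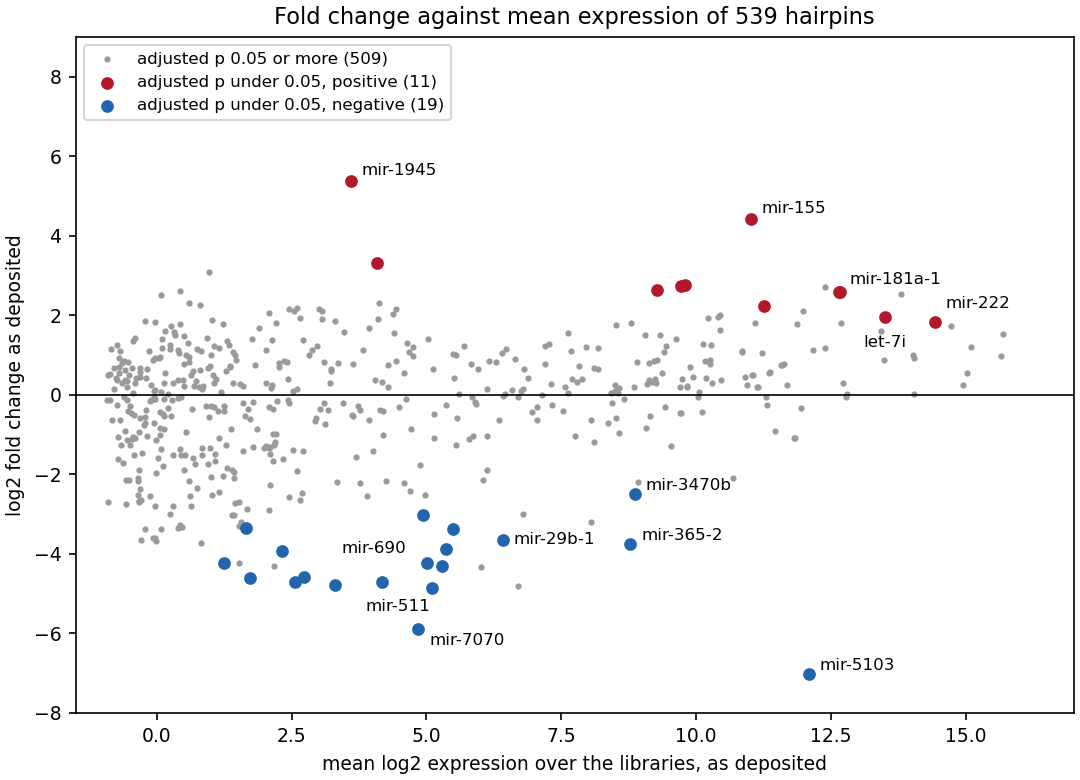
Log2 fold change (vertical axis) against mean log2 expression over the libraries (horizontal axis), both as deposited, for 539 hairpins. Called hairpins above a mean log2 expression of 8 are positive in 9 cases and negative in 3, which are mir-5103, mir-365-2 and mir-3470b.

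The most abundant hairpins did not pass the test. Averaged over both groups, mir-191 (15.69), mir-10a (15.65), mir-27b (15.09), mir-22 (15.02) and mir-21a (14.94) had the highest mean log2 expression in the authors' deposited table. Their log2 fold changes in the authors' deposited table were 1.54 (adjusted p = 0.107), 0.96 (0.621), 1.21 (0.168), 0.54 (0.629) and 0.24 (0.948). For mir-21a the 95% interval ran from −2.37 to 2.85, so a difference of several-fold either way is not excluded, and its sign turned to −0.10 after recentring by 0.34.

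Of 20 lists of miRNAs fixed before the data were examined, 19 had the 3 hairpins needed for a test against all other hairpins, and 4 passed an adjusted p of 0.05, all on the positive side. The list of lymphocyte markers had the smallest p (cameraPR of limma, adjusted p = 3.65e-06). That test counts copies of one miRNA as separate members, which makes its p too small. The list's adjusted p in cameraPR was 0.00230 with 1 hairpin per stem and 0.00441 on ranks. Of its 8 hairpins 4 passed over all hairpins and adjusted over the list alone, and those are the 4 copies of miR-181a and miR-181b. The other lymphocyte markers had positive log2 fold changes that did not pass in the authors' deposited table, with 2.31 for mir-181c, 1.86 for mir-181d, 0.64 for mir-29c and 0.59 (adjusted p = 0.910) for mir-150, the marker of mature lymphocytes. Macrophages also express miR-181 miRNAs. Against 10000 random lists matched on mean expression, this was the 1 list that passed (adjusted p = 0.00190, the smallest that 19 lists and this many draws allow). Each copy counts as a member there, and without the miR-181 hairpins too few of this list were left for a test.

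Inflammatory macrophage miRNAs, those induced through Toll-like receptors and NF-κB, were on the positive side as a list (cameraPR, adjusted p = 0.00990). Of its 11 hairpins, mir-155 alone passed, both over all hairpins and adjusted over the list alone. In the authors' deposited table the feedback regulators mir-146a and mir-146b were at 2.11 (adjusted p = 0.183) and 2.72 (adjusted p = 0.303), and mir-132 was at 0.90 (adjusted p = 0.480). Positive fold changes numbered 10 of 11, or 9 after recentring by 0.34. Because the direction of the table was taken from mir-155, the list was also tested without it, and the adjusted p was then 0.0546. The call was also lost when hairpins under a mean log2 expression of 3.32 were left out (adjusted p = 0.302) and against random lists of matched expression (adjusted p = 0.0627).

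The list associated with insulin resistance passed (cameraPR, adjusted p = 0.00502) with 17 of 20 hairpins positive, 14 after recentring by 0.34. Over all hairpins mir-155 and mir-222 passed on the positive side and mir-29b-1 on the negative side, and adjusted over the list alone 7 passed, 6 of them positive. In the authors' deposited table mir-222 was at 1.82 (adjusted p = 0.0240), its neighbour mir-221 at 1.72 (adjusted p = 0.123), mir-29a at 2.0 (adjusted p = 0.0614) and mir-27a at 1.80 (adjusted p = 0.0740). The hairpin mir-29b-1 was at −3.66 (adjusted p = 0.0310) in the authors' deposited table, and its copy mir-29b-2 at −0.54 (adjusted p = 0.896). While mir-29b-1 shares 20 bases with 1 other gene, this may be the host of mir-29b-2, which lies in an exon of A330023F24Rik. Published work ties mir-155 in this list to this same material, which makes it no independent evidence, and without mir-155 the list's adjusted p was 0.0257. The call was lost when hairpins under a mean log2 expression of 3.32 were left out (adjusted p = 0.203) and against random lists of matched expression (adjusted p = 0.237), and after recentring by 0.34 mir-222 no longer passed (adjusted p = 0.0704).

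The let-7 family passed by a small margin (cameraPR, adjusted p = 0.0314). Of its 12 hairpins let-7i alone passed, also adjusted over the list alone, while 11 were positive, or 9 after recentring by 0.34. Log2 fold changes in the authors' deposited table were 1.28 for let-7g (adjusted p = 0.201), 1.07 for let-7e (adjusted p = 0.202) and −0.33 for let-7d (adjusted p = 0.850). The call was lost with 1 hairpin per stem (adjusted p = 0.0611), with a preset correlation of 0.05 (0.10), after recentring by 0.34 (0.0634), above the expression minimum of 3.32 (0.302) and against random lists of matched expression (0.996).

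The miRNAs linked to alternative, interleukin-4 driven macrophage activation did not pass as a list (cameraPR, adjusted p = 0.900). Positive fold changes numbered 6 of 9, or 5 after recentring by 0.34, while the called members lay on the negative side. These are mir-511 and mir-690, 2 of 9 hairpins, and mir-690 shares 20 bases with 44 other genes. Adjusted over the list alone, mir-27a also passed, on the positive side. The authors' deposited table gives mir-223 at 1.54 (adjusted p = 0.307), mir-125a at 1.77 (adjusted p = 0.276) and mir-378a at 0.02 (adjusted p = 0.986; −0.32 after recentring by 0.34), so the list held members of both signs.

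**Figure D3:**
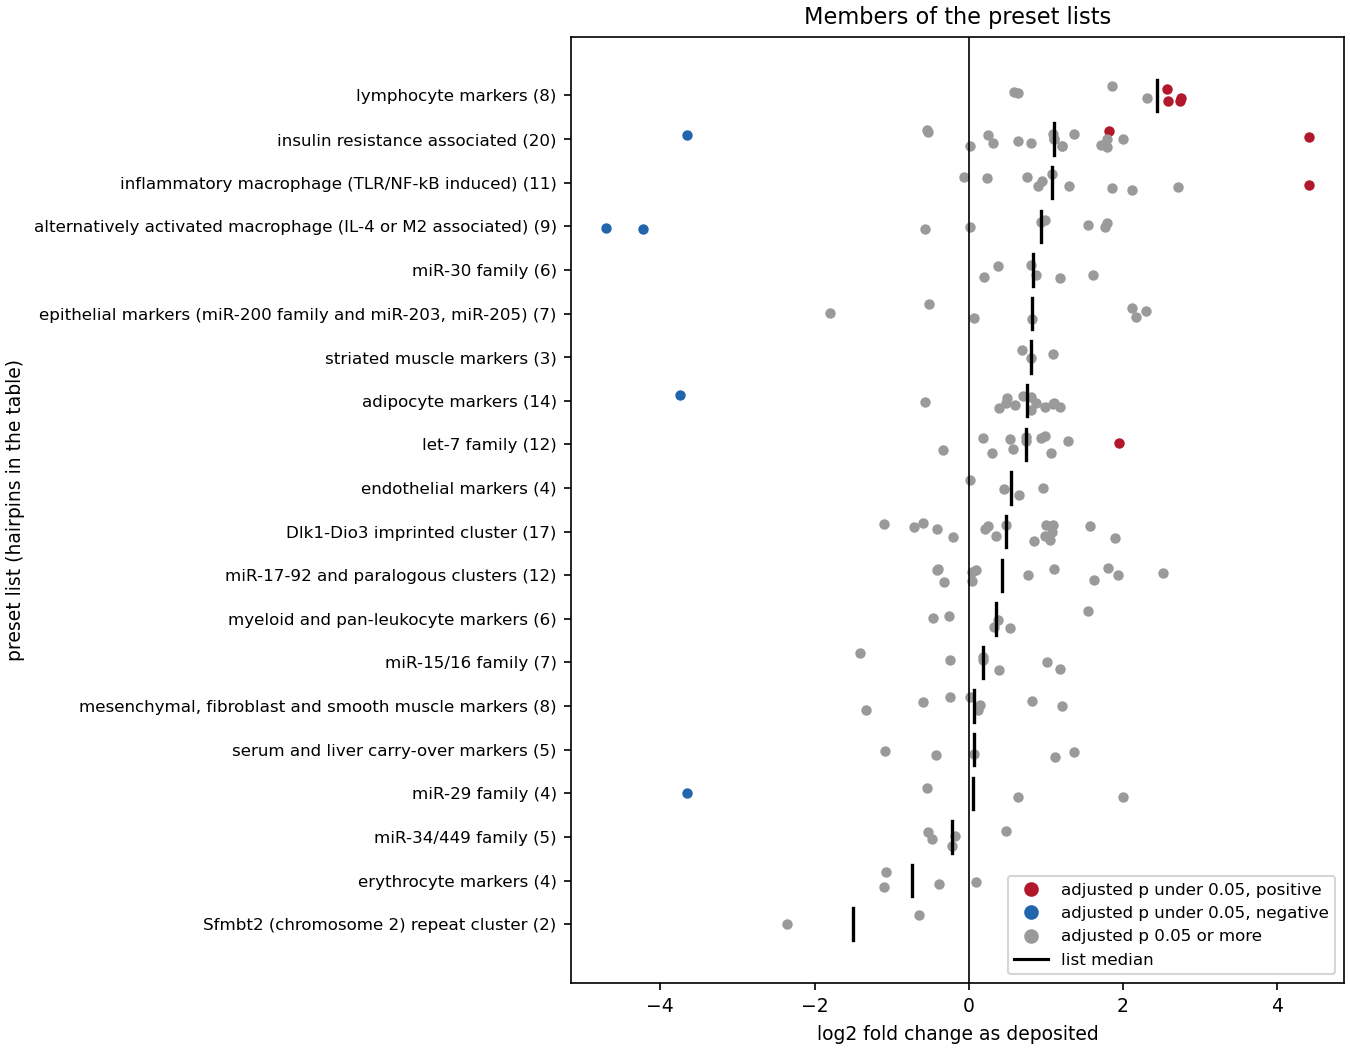
Log2 fold change as deposited (horizontal axis) of each hairpin in the 20 preset lists (vertical axis, with the number of hairpins in the table), coloured where the adjusted p over all hairpins is under 0.05, with a bar at the list median. The lymphocyte list has the highest median, 2.44, and its 4 coloured points are miR-181a and miR-181b copies.

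Of the marker lists for myeloid cells, which include macrophages, and for cells that a sort from fat could carry, only the lymphocyte list passed. None of the 6 myeloid and pan-leukocyte hairpins passed, over all hairpins or adjusted over the list alone (cameraPR, adjusted p = 0.734), with mir-223 at 1.54, mir-22 at 0.54 and mir-142a at −0.46 in the authors' deposited table. Among adipocyte markers (adjusted p = 0.318) mir-365-2 passed on the negative side, over all 539 and adjusted over the list alone. It stood at −3.75 (adjusted p = 0.0266) in the authors' deposited table, while its copy mir-365-1 was at 0.98 (adjusted p = 0.591). None passed, over all hairpins or adjusted over the list alone, among 4 endothelial (adjusted p = 0.734), 8 mesenchymal (0.954), 4 erythrocyte (0.719), 7 epithelial (0.426), 3 striated muscle (0.734) and 5 serum and liver carry-over hairpins (0.910). The erythrocyte miRNA mir-486a was at −1.09 (adjusted p = 0.526) and mir-451a at 0.09 (adjusted p = 0.965) in the authors' deposited table, and mir-451a turned to −0.25 after recentring by 0.34. The endothelial mir-126a was at 0.01 with a 95% interval from −4.01 to 4.04 in the authors' deposited table, and turned to −0.33 after the same recentring. The largest epithelial values in the authors' deposited table were 2.30 for mir-429 (adjusted p = 0.123) and 2.17 for mir-200b (adjusted p = 0.276), hairpins of mean log2 expression 0.60 and 2.45.

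The remaining families did not pass as lists either. The miR-17-92 cluster and its paralogs came nearest (cameraPR, adjusted p = 0.0598), with none of 12 hairpins past the threshold over all hairpins and 4 adjusted over the list alone. Those were mir-106b at 1.81, mir-92a-1 at 2.52, mir-93 at 1.62 and mir-25 at 1.11 in the authors' deposited table, whereas mir-17 was at 0.05, which turned to −0.29 after recentring by 0.34, and mir-20a at −0.32. The list passed when the miR-181 hairpins were left out of the table (adjusted p = 0.0440). Positive fold changes numbered 9 of 12 in this list, and 6 after recentring by 0.34. The miR-29 family (adjusted p = 0.963) held opposite members, mir-29b-1, with the shared sequence named above, and mir-29a, both past the threshold adjusted over the list alone, and its median of 0.05 differs in sign from its test, which was negative. The miR-30 family (adjusted p = 0.173), the miR-15/16 family (0.826), the families of miR-34 and miR-449 (0.910) and the imprinted Dlk1-Dio3 cluster (0.719) held no hairpin past the threshold, over all hairpins or adjusted over the list alone. The repeat cluster within Sfmbt2 had 2 hairpins in the table, too few for a test, with mir-466i at −2.36 (adjusted p = 0.355) and mir-466f-1 at −0.65 (adjusted p = 0.896) in the authors' deposited table.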

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

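The 2-fold minimum and the adjusted p under 0.1 were planned, and the other alternatives were chosen after seeing the data. No paired analysis was possible because the table has no values per library. For the same reason other scalings, filters on counts, other tests, leaving out a library, other splits of the libraries, other pseudocounts, fry and an estimated correlation were not run, and depth cannot be set against any call. Calls numbered 30 at 2-fold, 45 at an adjusted p under 0.1 (19 positive), 32 above a mean log2 expression of 3.32, 26 with 1 hairpin per stem, 29 and 33 with recentring by 0.09 and 0.34, and 15 (6 negative) without hairpins that share sequence, where 12 of the 30 are left out by construction. Recentring by 0.34 shared 27 of the 30 calls, lost 3 and gained 6. The hairpin mir-155 stayed past the threshold on the positive side in the alternatives that tested it. These reuse its deposited values, and the shifts are small beside its log2 fold change of 4.41. They therefore do not show how mir-155 depends on the authors' processing. Of the hairpins named in the text, those that turned did so with recentring by 0.09 (mir-126a to −0.078, mir-17 to −0.045, mir-378a to −0.070) and by 0.34 (mir-126a to −0.33, mir-451a to −0.25, mir-21a to −0.10, mir-17 to −0.29, mir-378a to −0.32), which the shift itself produces. Above the expression minimum, where fewer hairpins are tested, mir-106b and mir-29a (adjusted p = 0.0348), mir-27a (0.0407) and mir-92a-1 (0.0396) passed. Passing lists numbered 1 above the expression minimum or against random lists of matched expression, and 3 or 4 in the other settings. The lymphocyte list passed in each setting that left it 3 hairpins. Without the miR-181 hairpins it had too few for a test, so its passes rest on the miR-181 family. Lost calls, as adjusted p, were above the expression minimum 0.302 (inflammatory and let-7) and 0.203 (insulin resistance), against matched lists 0.0627, 0.237 and 0.996 (inflammatory, insulin resistance, let-7), without mir-155 0.0546 (inflammatory), and for let-7 0.10 with the higher correlation, 0.0611 with 1 hairpin per stem and 0.0634 with recentring by 0.34. The miR-17-92 list passed without the miR-181 hairpins (0.0440). Lists that never passed turned in direction above the expression minimum at 0.908 (alternative activation, mesenchymal, miR-15/16, serum and liver), with 1 hairpin per stem at 0.929 (mesenchymal, miR-29, serum and liver), on ranks at 0.999 (miR-29) and without the miR-181 hairpins at 0.995 (miR-29). Apart from the shifts and omissions named, the cause was not tested.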

Other observations

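Neighbouring hairpins tended to have similar t values, which includes pairs with both members near 0. Of the tests in this part, those of the split into negative and positive calls, of that split after removal of the GC trend, of low expression, of a single scaling factor and of the more abundant and the less similar neighbour pairs were chosen after the result was seen. The pair mir-221 and mir-222, 505 bases apart on chromosome X, stood at 1.72 and 1.82 in the authors' deposited table, and mir-93 and mir-106b, 127 bases apart on chromosome 5, at 1.62 and 1.81. Likewise mir-191 and mir-425, 385 bases apart on chromosome 9, were at 1.54 and 1.22 in the authors' deposited table. Of these, mir-222 alone passed an adjusted p of 0.05. Over 74 pairs of adjacent hairpins of different stems within 10 kb on a strand that share no stretch of 16 bases, the mean absolute difference in t was 1.07, against 1.88 in random pairings (one-sided permutation p = 0.0001, the smallest that 10000 permutations can give). Of these pairs 48 had the same sign and 26 opposite signs, but no count from random pairings was set beside this. Positive values prevailed among these hairpins, which alone raises the number of same signs. Among the 36 pairs with both members above a mean log2 expression of 3.32 the mean absolute difference in t was 1.19 against 2.14 (one-sided permutation p = 0.0005). Similar sequence, as in miR-181a and miR-181b, does not account for all of it: over 47 pairs that share no 9 bases in sense, each pair of stems taken once, it was 0.936 against 1.88 (one-sided permutation p = 0.0001). Thus shared transcription may carry over into the exosome profile, a hypothesis that these data cannot set against shared library effects.

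Among the pairs of opposite sign, the widest gap in t was between mir-29a and mir-29b-1, 276 bases apart on chromosome 6 and processed from a common primary transcript, and these stood at 2.0 and −3.66 in the authors' deposited table. Copies of one miRNA differed little as a rule, with a median difference of 0.12 in log2 fold change over 29 stems. Since copies can share mature reads, this may follow from how reads were assigned, which is not known. In 5 stems the difference was above 1, with the widest gaps in mir-365 (0.98 and −3.75), mir-29b (−0.54 and −3.66) and mir-194 (1.11 and −1.08), from the authors' deposited table. No explanation was tested for these gaps.

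Negative calls outnumbered positive ones, 19 to 11, a split for which chance is not excluded (exact binomial test, two-sided p = 0.200), and many are hairpins whose sequence recurs in other RNAs. GC content stays open: the median GC of placed negative calls was 56.2%, against 52.7% for hairpins not called (two-sided permutation p = 0.179). Of those calls 15 of 18 still passed after a linear GC trend was removed, which was to count against it, but that bound followed single calls and not the excess, and 17 negative and 15 positive calls were left. Shared sequence stays open as well: 61.1% of the placed negative calls (95% exact interval 35.7% to 82.7%) share 20 bases with another gene, against 15.6% of hairpins not called (Fisher's exact test, two-sided p = 2.56e-05) and 9.09% of positive calls (p = 0.00800). Low expression stays open too, as 16 negative and 16 positive hairpins were called above a mean log2 expression of 3.32. A candidate explanation is that fragments of messenger RNAs such as Ftl1 and of repeats, counted as hairpins, differ between the groups, and a difference between obese and lean ATMs in such fragments is untested here.

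The median log2 fold change was higher among abundant hairpins, though not as a graded trend: it was 0.34 in the 180 most abundant, −0.30 in the 179 in the middle and −0.12 in the 180 least abundant. The most abundant included 9 positive and 7 negative calls, and whether their median lies above 0 depends on the scaling of the groups. The difference from the least abundant was 0.46 (bootstrap 95% interval 0.14 to 0.78), but rows near the floor can hide a common shift. Among hairpins above a mean log2 expression of 3.32, the median was 0.54 in the 116 more abundant and −0.023 in the 115 less abundant, a difference of 0.56 (0.23 to 1.0), which argues against a single scaling factor as the whole cause, though the depth behind the less abundant is unknown. The bootstrap intervals describe the spread over hairpins, not between libraries. Since copies and neighbours tend to have similar values, these intervals may be too narrow. Without hairpins that share sequence, the difference between the most and the least abundant was 0.54 (0.23 to 0.90), so these do not account for that difference. The comparison above 3.32 was not repeated without them, so shared sequence stays open there. A difference between the groups in miRNA content may lie behind the higher median of abundant hairpins and was not tested.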
